A study of Mus musculus with 4 samples.

How the data were processed

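The series holds 4 ribosome profiling libraries of mouse epidermal keratinocytes taken at postnatal day 0, 2 from control mice (Ctrl) and 2 from conditional Mettl14 knockout mice (cKO). Per the labels' protocols, cells were lysed in the presence of cycloheximide, which holds ribosomes on their mRNA, the lysate was digested with RNase I, and protected fragments of 25 to 35 nt were selected on a gel before library preparation. Cycloheximide itself can shift where ribosomes sit, and a footprint count mixes mRNA level with ribosome density. The protocols also describe libraries of total RNA; total RNA values and translational efficiency were not analysed here, so the tests planned for them were not run. Per the submitters' processing notes the tools were fastp, HISAT2 and HTSeq and the build was GRCm38; their versions, the counted feature, the strand setting and any filter on footprint length are not given in the sources used here.

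The deposited table gives CPM values (reads of a gene scaled to a library total of 1000000) per gene and library, computed by the authors over the listed genes alone, since each column sums to 1000000 over its 10327 genes. No scaling between libraries was seen in the values. Every value was a whole multiple of the value of 1 read (tolerance 1e-06 reads, 100% of values), so whole reads were recovered: 933574 in Ctrl 1, 624167 in Ctrl 2, 542074 in cKO 1 and 751948 in cKO 2, where 1 read is worth 1.07, 1.60, 1.84 and 1.33 CPM. All listed genes had at least 1 read in every library, so genes lost altogether from any library are not analysed here. Depth limits low genes: 2256 genes in Ctrl 1, 3012 in Ctrl 2, 4145 in cKO 1 and 3163 in cKO 2 had under 10 reads. The table's header calls the control columns WT, which were taken as the Ctrl samples of the same number because the labels have no other group. The libraries of a group differed by more than counting noise (chi-square per degree of freedom 3.69 for Ctrl and 3.13 for cKO), which separate preparations of 1 sample would do too, and they were taken as replicates because the labels number them so.

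Gene identifiers were matched to symbols, positions and coding sequence of the GENCODE annotation for GRCm38; 10323 of 10327 matched, and 10317 were protein coding. Exons of 3783 genes overlap those of another gene, and because the strand setting is not given, reads of such genes cannot be assigned with certainty.

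The main test was chosen for CPM values: limma 3.58.1 with a mean-variance trend on log2(CPM + 1), group as the only term and no block, in R 4.3.3. A fold change on this scale understates the change of genes with low values. Genes with 1 CPM or more in at least 2 libraries were kept, which removed 0 genes. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. With 2 against 2 libraries the smallest two-sided p of an exact permutation test is 0.333, so single-gene permutation tests were not used. Standard errors are those of limma, and SD is over the 2 libraries of a group. Because the median gene had a log2 change of -0.245, changes are also given relative to that median or after median centring.

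Before the data were examined, 31 gene lists, the alternatives and the naming rule were fixed. The rule names Mettl14, Col17a1, Itga6 and Itgb4; the 10 called genes with the highest and the 10 with the lowest log2 change among those at or above the median expression (28.1 CPM) whose cKO libraries lie both above or both below the Ctrl libraries; and for each list up to 4 called members (the 2 largest rises and the 2 largest falls) or, if none is called, the 2 most abundant. Of the genes the rule names, 1 is not reported here. Genes named because they passed over a list alone lie outside that rule and were named after their values were seen. Lists with 5 or more measured genes, 28 in all, were tested against all other genes with camera of limma at a preset correlation of 0.01 between genes and adjusted over the 28 lists; 6 passed above other genes and 8 below. With the correlation estimated from these 4 libraries, camera called 0 lists (smallest adjusted p = 0.415, with 2 lists at an unadjusted p under 0.05), so no list call holds under that setting. That setting also takes its degrees of freedom from the 4 libraries rather than the genes, so small p-values are hard to reach. The estimate lay below the preset value for the basal (-0.052) and hemidesmosome (-0.020) lists, whose lost calls are thus not due to correlation between genes. Failing under it does not show that a list did not move.

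On data simulated for this comparison (5 runs of about 9875 genes, 200 changed in each), limma called 69.3% of genes changed 4-fold (95.4% among genes above the median expression) and 18.4% of genes changed 2-fold, and 6.79% of its calls were false. Of 100 simulated lists without a change camera called 0, and of 5 with one it called 5. In those 5 all 20 genes were raised 2-fold in cKO. They do not show how often camera would find shifts as small as that of the oxidative phosphorylation list (a median of -0.18 relative to all genes). The simulated genes varied independently of each other, whereas the estimated correlation reached 0.77 in the histone list and 0.52 in the fibroblast list. These counts therefore do not give the rate of false calls for lists of correlated genes.

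The alternatives fixed beforehand were the replicate number as a block, leaving out each library, upper quartile scaling, median centring, limma without trend, no filter and a filter of 10 CPM, pseudocounts of 0.1 and 5, adjusted p under 0.1 and 0.01, and leaving out the 50 most abundant genes. Added after the values were seen were edgeR 4.0.16 (quasi-likelihood test with TMM, library totals or DESeq2 size factors) and DESeq2 1.42.0 on the recovered reads, TMM factors in limma, and the block with TMM or centring. The plan fixed beforehand had named edgeR with TMM and an expression filter for raw counts, and limma where only normalized values were given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.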

Results

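Ribosome profiling was carried out on epidermal keratinocytes from newborn mice at postnatal day 0. In this assay the lysate is digested with RNase and the stretches of mRNA shielded by ribosomes, called footprints, are sequenced, so that a gene's value is its share of all footprints. The 4 libraries formed 2 groups of 2. Control mice (Ctrl) carried a K14-driven Cre transgene, active in basal keratinocytes, and were heterozygous for a floxed Mettl14 allele. Conditional knockout mice (cKO) carried the same Cre and 2 copies of the floxed allele. METTL14 is a core subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. The deposited values were CPM (a gene's reads scaled to a library total of 1000000) for 10327 genes, each with at least 1 read in every library. The recovered read totals were 933574 in Ctrl 1, 624167 in Ctrl 2, 542074 in cKO 1 and 751948 in cKO 2, and the median gene had 27, 19, 14 and 19 reads in that order. The labels do not state that the libraries of a group came from separate animals, so the spread between them may be technical. The limma test also draws each gene's variance toward a trend over genes of like abundance. Its standard errors and p-values therefore do not measure a gene's own spread alone, and they do not reach beyond these samples.

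Mettl14 was examined in every library, since it checks the genotype labels. Mettl14 (ENSMUSG00000028114, chromosome 3, 123368297 to 123386108, minus strand, GRCm38) had 26 reads in Ctrl 1 and 17 in Ctrl 2, against 5 in cKO 1 and 4 in cKO 2. Its mean was 27.5 ± 0.43 CPM in Ctrl and 7.27 ± 2.76 CPM in cKO (SD, n = 2 each), and both cKO libraries lay below both Ctrl libraries. The log2 change of -1.83 ± 0.55 (SE) did not pass the main test over all genes (limma without a block, Benjamini-Hochberg adjusted p = 0.122), with few reads behind each cKO value. With the replicate number as a block, a pairing that no label gives, limma called it lower (adjusted p = 0.0178). The floxed part of the gene is not used here, so footprints from outside it count toward these values.

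The comparison of cKO with Ctrl asks how loss of METTL14 alters ribosome occupancy in the epidermis, and the series names Col17a1, Itga6 and Itgb4 as its genes of interest. Collagen XVII and the paired integrins Itga6 and Itgb4 are transmembrane parts of the hemidesmosome, the junction that anchors basal keratinocytes to the basement membrane. For all 3 genes both cKO libraries lay below both Ctrl libraries, yet none passed limma without a block over all genes. With the replicate number as a block, limma called all 3 lower (adjusted p = 3.35e-05 for Col17a1, 3.19e-05 for Itgb4 and 0.0199 for Itga6), but no label pairs equally numbered samples. Col17a1 (ENSMUSG00000025064, chromosome 19, 47646344 to 47692094, minus strand) had 1338 ± 58.2 CPM in Ctrl and 749 ± 59.9 CPM in cKO (SD, n = 2), a log2 change of -0.84 ± 0.20 (SE; limma adjusted p = 0.0531). Itgb4 (ENSMUSG00000020758, chromosome 11, 115974709 to 116008412, plus strand) had 887 ± 174 and 481 ± 18.6 CPM, a log2 change of -0.87 ± 0.21 (limma adjusted p = 0.0531). Itga6 (ENSMUSG00000027111, chromosome 2, 71745616 to 71858416, plus strand) had 649 ± 140 and 455 ± 115 CPM, a log2 change of -0.52 ± 0.23 (limma adjusted p = 0.305). The genes' exons lie within these annotated spans, and those of Itgb4 overlap the annotated gene B230344G16Rik, so its reads may be shared. With library totals on the recovered reads, edgeR called Col17a1 (adjusted p = 0.0458) and Itgb4 (0.0434) lower, but it called neither with TMM (0.225 and 0.195), nor did limma after centring (0.172 for each). Itga6 stood at -0.29 without Ctrl 1 and at -0.26 without cKO 2. Relative to the median of all genes, which lay at a log2 change of -0.245, the 3 changes were -0.59 for Col17a1, -0.62 for Itgb4 and -0.27 for Itga6.

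Of the 6 hemidesmosome genes, 4 were lower in cKO when p-values were adjusted over the list alone (Col17a1, Dst, Itga6 and Itgb4; 2 after centring), and none when adjusted over all genes. Col17a1, Itga6 and Itgb4 are the study's own choice, so this count is not independent evidence of the direction. Dst, a linker to keratin filaments, had a log2 change of -0.64 (-0.32 without Ctrl 1), and Plec, another such linker, had 0.14, and neither passed over all genes. Cd151, the remaining member, had a log2 change of -0.11 with overlapping libraries. As a set the list stood below other genes by a median of -0.33 (camera adjusted p = 0.0138, but adjusted p = 0.498 with an estimated correlation). The call was absent after median centring (camera adjusted p = 0.0655) and without Ctrl 1, cKO 1 or cKO 2. The list's median was -0.024 without Ctrl 1, -0.35 without cKO 1, -0.32 without cKO 2 and -0.54 without Ctrl 2. Fibroblast markers, taken as a list for another cell type, had a median of -0.61 relative to all genes (adjusted p = 0.502 with an estimated correlation), but of -0.0076 without Ctrl 1.

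**Figure D1:**
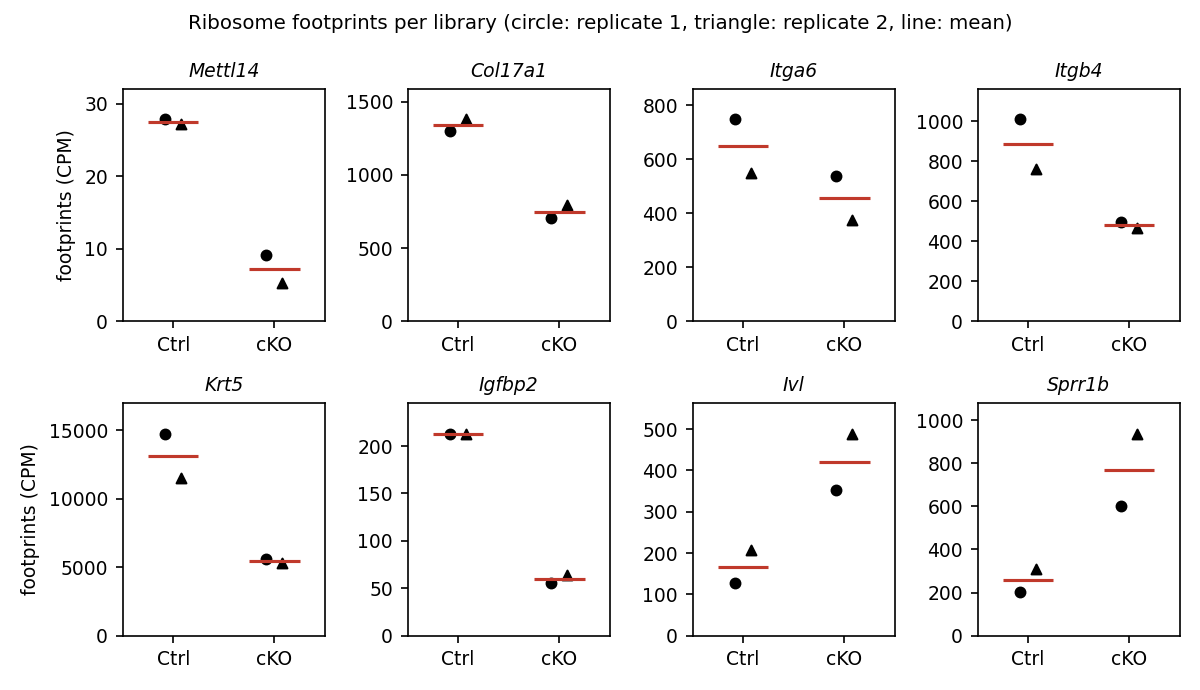
Footprints in CPM (vertical axes, from 0) of 8 genes in the 4 libraries; circles are replicate 1, triangles replicate 2, and red lines the mean of each group of 2. The cKO libraries lie below both Ctrl libraries for Mettl14, Col17a1, Itga6, Itgb4, Krt5 and Igfbp2 and above both for Ivl and Sprr1b; of these, Krt5, Igfbp2, Ivl and Sprr1b passed the test over all genes.

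Over all genes, 38 rose and 31 fell at a Benjamini-Hochberg adjusted p under 0.05, of 10327 tested by limma, while 1475 genes had an unadjusted p under 0.05. The highest-ranking rises were those of Tent5b, a member of a family of noncanonical poly(A) polymerases, and Cldn23, a claudin of tight junctions, with log2 changes of 2.28 ± 0.33 and 1.80 ± 0.36 (SE), although Cldn23 did not pass without Ctrl 1 (1.08, adjusted p = 0.139). Susd2, a membrane protein with a sushi domain (ENSMUSG00000006342, chromosome 10, 75636706 to 75644008), rose from 273 ± 25.9 to 856 ± 62.0 CPM (SD, n = 2), a log2 change of 1.65 ± 0.20 with the smallest adjusted p of the table (limma, 0.000524). The epithelial sodium channel subunits Scnn1b and Scnn1a rose by 1.66 and 1.47 on the log2 scale. Igfbp2, an insulin-like growth factor binding protein (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), fell from 213 ± 0.050 to 59.6 ± 6.0 CPM, a log2 change of -1.82 ± 0.25 (limma adjusted p = 0.00157).

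The remaining genes among the 10 with the highest and the 10 with the lowest changes were of varied function. Mpzl3, an immunoglobulin-like membrane protein, rose by 1.71, Prss27, a serine protease, by 1.59, Sprr1b, a small proline-rich precursor of the cornified envelope, by 1.58, Metrnl, a secreted protein, by 1.5 and Krt16, a keratin of stressed epidermis, by 1.42 on the log2 scale. Kremen2, a receptor for Dickkopf inhibitors of Wnt signalling, fell by 1.63, Capn6, a calpain without protease activity, by 1.54 and Atp6v1b1, a proton pump subunit, by 1.51. Lef1, a transcription factor of Wnt signalling, fell by 1.43, Fxr1, an RNA-binding protein, by 1.39, and Ccna2, the S and G2 phase cyclin A, by 1.35. Dcn and Sparc, proteins of the extracellular matrix, fell by 1.34 and 1.31, and Mthfd1, an enzyme of folate metabolism, by 1.27. Adjusted p-values of these genes ran up to 0.0469 (limma, for Lef1). Kremen2 did not pass without Ctrl 2 (adjusted p = 0.341), nor Capn6 (0.44), Fxr1 (0.262) and Mthfd1 (0.0670) without Ctrl 1. Exons of Kremen2, Capn6, Lef1, Fxr1, Ccna2, Mthfd1 and Mpzl3 overlap those of another annotated gene, so their values are less certain. Outside the naming rule, Plekhh2 had the most negative log2 change among the genes called, -2.75 (limma adjusted p = 0.0373), on 1 and 5 reads in cKO and 30 and 18 in Ctrl, and it was singled out after its values were seen.

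The split between rises and falls depended on the scaling. On the deposited scale 55.1% of the 69 called genes were higher, but after median centring 105 genes rose and 8 fell, so that 92.9% were higher. The median log2 change of all genes was -0.245 as deposited, -0.0365 after centring and 0.0018 with edgeR and TMM. Such an upward shift enlarges rises and shrinks falls, so passing there is no independent check of the rises. A lost call likewise does not show that a fall was absent. All 38 rising genes also passed after centring and with edgeR on the recovered reads (163 higher and 13 lower). Of the 31 falling genes, 8 passed after centring and 10 with edgeR. The 8 were Plekhh2, Igfbp2, Atp6v1b1, Dcn, Sparc, Nasp, Col12a1 and Gpc3, of which Nasp, Col12a1 and Gpc3 were named after their values were seen. Krt1 and Krt10, the main keratins of suprabasal cells, together took 12.5% of reads in Ctrl 1 (95% exact binomial interval 12.41 to 12.54%), 11.1% in Ctrl 2 (11.03 to 11.18%), 17.9% in cKO 1 (17.78 to 17.99%) and 16.4% in cKO 2 (16.32 to 16.48%), and these intervals cover counting error only. Both cKO libraries lay above both Ctrl libraries for 11.1% of genes and below both for 34.1%, where chance gives 33.3% for the 2 directions together. No gene passed limma without cKO 1 (smallest adjusted p = 0.532; 940 genes at an unadjusted p under 0.05) or without cKO 2 (0.552; 928 genes). Without Ctrl 1 there were 20 higher and 44 lower, and without Ctrl 2 there were 104 higher and 35 lower.

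**Figure D2:**
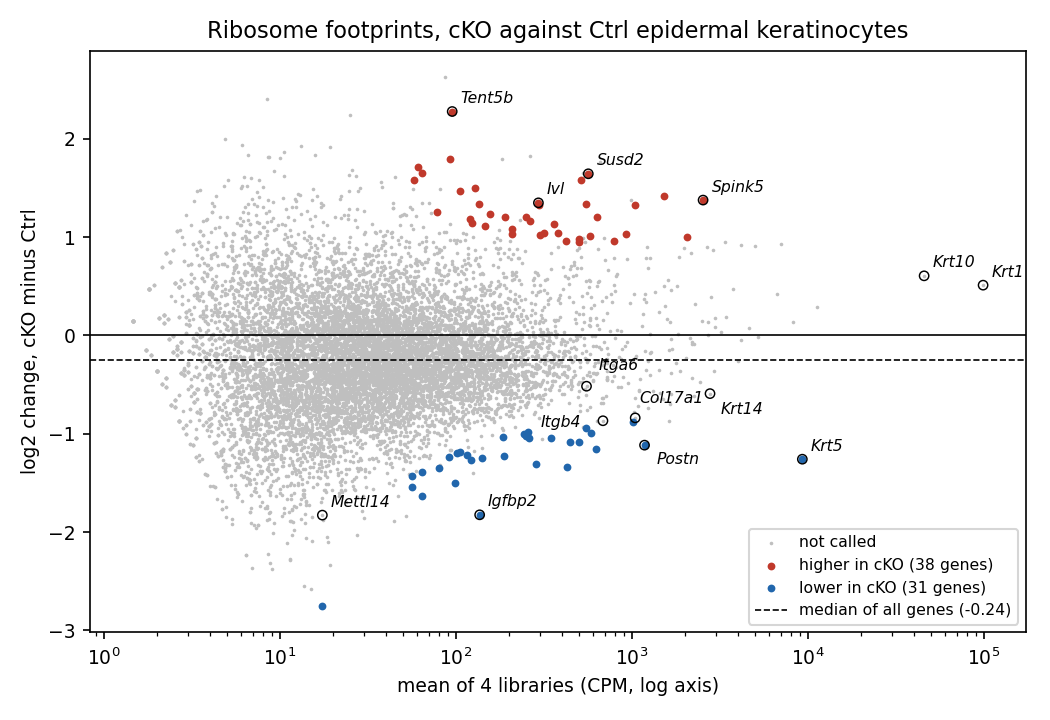
Log2 change of cKO against Ctrl (vertical axis) by mean CPM of the 4 libraries (horizontal log axis), 1 point per gene; red points are the 38 genes called higher, blue points the 31 called lower, grey points the rest, the solid line 0 and the dashed line the median of all genes. The bulk of the grey points is centred on the dashed line at -0.245, and circled genes carry their names.

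The granular and cornified list holds genes whose products build the cornified envelope and the lipid barrier. Of its 38 measured members, 7 rose by limma (Alox12b, Ivl, Klk5, Rptn, Spink5, Sprr1b and Tgm3), none fell and 31 did not pass, with a negative log2 change in 12. Most of these 12 were Lce1 genes, and no measured Lce1 gene had a log2 change above 0.087 (Lce1i). Adjusted over the list alone, 20 rose. Spink5, an inhibitor of epidermal serine proteases, rose by 1.38 ± 0.27 (SE) on the log2 scale, from 1385 ± 465 to 3688 ± 1646 CPM (SD, n = 2), and Sprr1b rose by 1.58 ± 0.24. The list's median stood 1.01 above that of all genes (camera adjusted p = 8.63e-21, but adjusted p = 0.498 with an estimated correlation). No member of the spinous list (15 measured) passed limma over all genes, whereas edgeR called Dmkn, Dsc1, Dsg1b and Sbsn higher, and 5 were higher when adjusted over the list alone (Dmkn, Dsc1, Dsg1b, Sbsn and Skint3), and its median stood 0.76 above that of all genes (adjusted p = 2.66e-09, but adjusted p = 0.415 with an estimated correlation). Krt1 and Krt10 themselves had log2 changes of 0.51 ± 0.48 and 0.61 ± 0.39 (SE) and did not pass. For each of them both cKO libraries lay above both Ctrl libraries. Krt10 had 36249 ± 809 CPM in Ctrl and 55220 ± 923 CPM in cKO (SD, n = 2). Its standard error thus owes more to the trend over genes than to the spread between its libraries. After centring, 16 granular and 4 spinous genes rose. Without Ctrl 1, Spink5 no longer passed (log2 change 1.03, adjusted p = 0.104). Haemoglobin genes, the markers of red blood cells, were high in cKO 1 (Hba-a1 at 218 CPM, against 39.9 in cKO 2, 43.9 in Ctrl 1 and 24.0 in Ctrl 2).

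Of 17 measured members of the basal list, 3 fell by limma (Igfbp2, Krt5 and Bcam) and 14 did not pass, and after centring 1 passed. Adjusted over the list alone, 8 fell (6 after centring), Col17a1 and Itgb4 among them. Bcam did not pass after centring (adjusted p = 0.0763) or with edgeR (0.0978). Krt5, the basal partner keratin of Krt14 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand), fell from 13141 ± 2277 to 5451 ± 184 CPM (SD, n = 2), a log2 change of -1.26 ± 0.27 (SE; limma adjusted p = 0.0293) and of -1.01 relative to the median of all genes. Its call was absent after centring (adjusted p = 0.0677) and without Ctrl 1 (log2 change -1.08, adjusted p = 0.202), and present with edgeR and TMM (-1.02, adjusted p = 0.0175). The list's median stood at -0.39 relative to all genes (camera adjusted p = 1.15e-07, but adjusted p = 0.415 with an estimated correlation). The desmosome and adherens junction list had no member past the test among 15 (camera adjusted p = 0.695), with Dsp at 0.29 and Perp at 0.42. Fibroblast markers had a median of -0.61 relative to all genes, and without Ctrl 1 they stood at -0.0076 and the basal list at -0.38. The fibroblast markers called lower, Dcn, Sparc and Postn, kept a median log2 change of -1.13 without Ctrl 1.

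Of 26 measured basement membrane and matrix receptor genes, 1 fell by limma, Frem2, a protein of the epidermal basement membrane (log2 change -0.89 ± 0.20, SE; limma adjusted p = 0.0393; 0.123 after centring; 0.0714 without Ctrl 1 and 0.143 without Ctrl 2), and 25 did not pass. Adjusted over the list alone 11 fell (3 after centring), among them chains of laminin (Lama3, Lama5, Lamb1 and Lamb3) and integrins (Itga2 and Itga3). The list's median stood at -0.23 relative to all genes (camera adjusted p = 1.59e-06, but adjusted p = 0.415 with an estimated correlation), and at -0.12 without Ctrl 1. Of 24 hair follicle genes, 1 fell (Lef1), and 5 were lower when adjusted over the list alone (1 after centring): Edar, Krt17, Lef1, Shh and Wnt10b, which include signals of hair germ formation. That list stood at -0.21 (camera adjusted p = 0.0364, but adjusted p = 0.687 with an estimated correlation), and its call was absent after centring (0.0659), without Ctrl 1 and without cKO 1. With 1 library left out its median ran from -0.42 (without cKO 2) to -0.17 (without Ctrl 1). Lef1 did not pass after centring (adjusted p = 0.0861), without Ctrl 1 (0.0672) or without Ctrl 2 (0.292). Fibroblast markers stood at -0.61, but at -0.0076 without Ctrl 1.

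Of 35 measured proliferation genes, 1 fell (Ccna2, limma adjusted p = 0.0393; 0.0779 after centring; 0.25 without Ctrl 2), and 15 fell when adjusted over the list alone (1 after centring), including Pcna, Top2a and Mcm2 to Mcm6 of DNA replication. The list stood at -0.39 relative to all genes (camera adjusted p = 1.68e-08, but adjusted p = 0.415 with an estimated correlation). Of 20 replication-dependent histone genes, 1 fell (Hist1h1a, a linker histone, log2 change -1.04 ± 0.24, SE; 0.0971 after centring; -0.67, adjusted p = 0.364, without Ctrl 2) and 8 fell when adjusted over the list alone (1 after centring). Copies of these genes are nearly alike, so single values are uncertain. The histone list stood at -0.50 (camera adjusted p = 3.68e-06, but adjusted p = 0.616 with an estimated correlation), but at -0.045 without Ctrl 2 (adjusted p = 0.455) and at -0.19 without cKO 1 (0.191). The 48 nuclear genes of oxidative phosphorylation had no member past the test and stood at -0.18 (camera adjusted p = 0.000831; adjusted p = 0.502 with an estimated correlation; 0.0618 without cKO 1). Their most abundant members, the ATP synthase subunits Atp5b and Atp5a1, had log2 changes of -0.39 and -0.40. Beside these lists, fibroblast markers stood at -0.61 (-0.0076 without Ctrl 1) and red blood cell genes 1.38 above all genes (0.37 without cKO 1).

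Of 16 measured wound and alarmin genes, 1 rose by limma, Krt16, from 808 ± 73.5 to 2225 ± 765 CPM (SD, n = 2; log2 change 1.42 ± 0.23, SE; limma adjusted p = 0.00556). Adjusted over the list alone, 5 were higher (Il33, Krt16, Krt6a, Krt6b and Stfa2) and 1 lower (Krt17, which the hair follicle list also holds). The list stood 0.92 above all genes (camera adjusted p = 9.55e-06; adjusted p = 0.502 with an estimated correlation; 0.107 without cKO 2, at a median of 0.55), and 0.32 above without Ctrl 1. With edgeR, Krt6a, Krt6b and Stfa2 were also higher. Krt6a and Krt6b are near-identical copies whose reads cannot be apportioned with certainty, and Ctrl 2 (405 and 477 CPM) lay above cKO 1 (290 and 275 CPM) for both. Beside this list, fibroblast markers stood at -0.61 and red blood cell genes 1.38 above all genes. None of 21 cholesterol synthesis genes passed limma, with or without adjustment over the list alone, but 20 lay above the median of all genes, and the list stood 0.64 above it (camera adjusted p = 3.30e-08, but adjusted p = 0.502 with an estimated correlation), and 0.42 above without cKO 2. After centring, 8 of them were higher when adjusted over the list alone, and the abundant members Hmgcs1, an early enzyme of the pathway, and Srebf2, its transcription factor, had log2 changes of 0.24 and 0.43 relative to the median of all genes. The unfolded protein response list had no gene past the test among 18 and stood 0.33 above all genes (camera adjusted p = 0.0305; adjusted p = 0.725 with an estimated correlation; 0.749 without Ctrl 1 and 0.337 without cKO 2), with Pdia3 at 0.30 and Hspa5 at 0.42 (0.090 without Ctrl 1 and 0.076 without cKO 2).

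**Figure D3:**
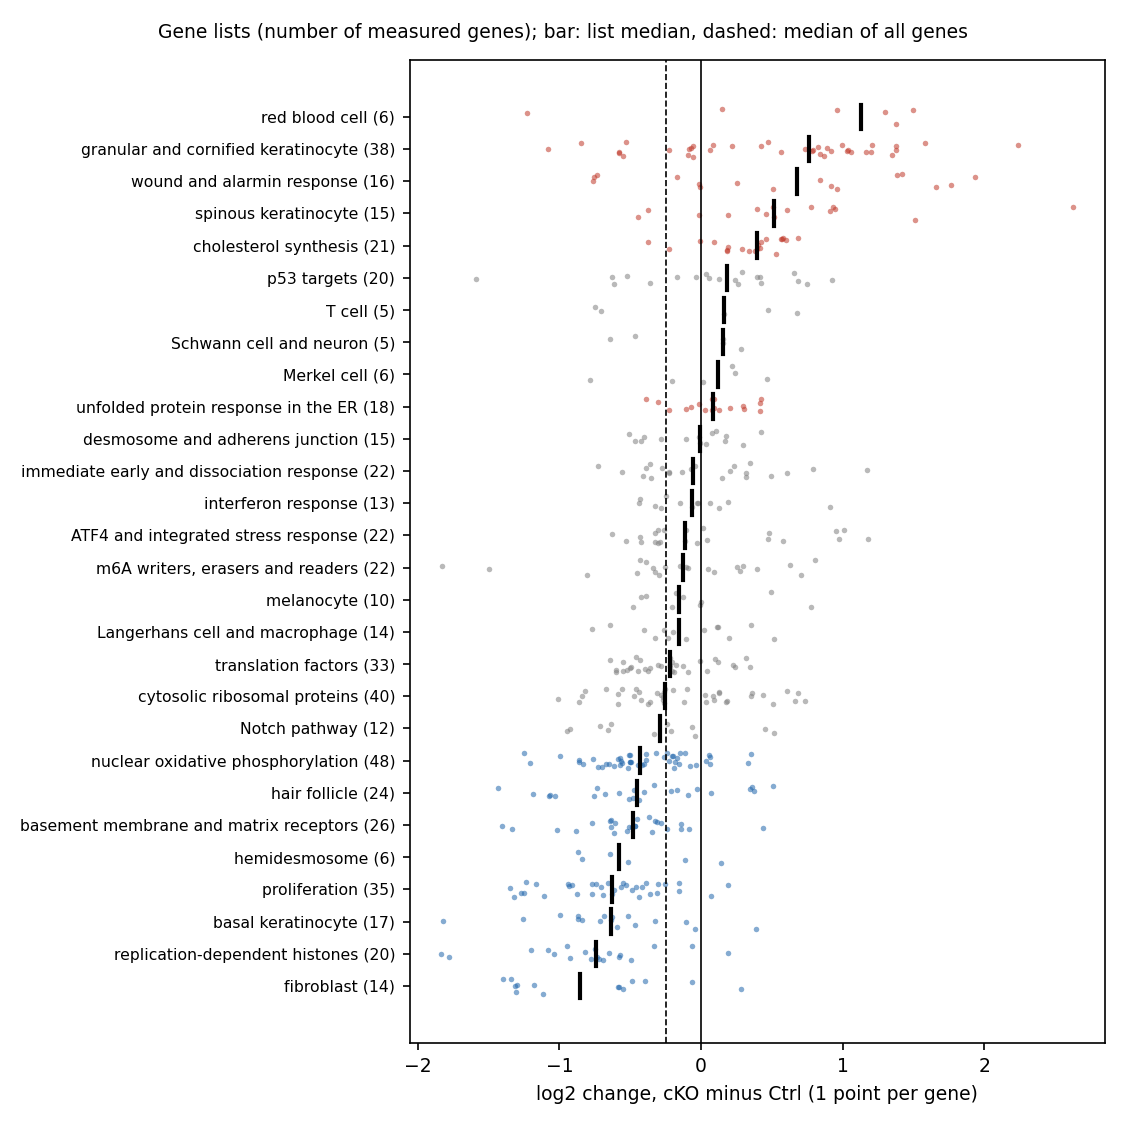
Log2 change of cKO against Ctrl (horizontal axis) of the measured members of the 28 lists tested by camera, 1 point per gene, with the number measured in parentheses; black bars are list medians, the solid line 0 and the dashed line the median of all genes at -0.245. Red lists passed camera above other genes, blue lists below, and grey lists did not pass; the granular and cornified list has its median 1.01 above the dashed line and the basal list 0.39 below it, at -0.64.

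The m6A list and the other pathway and immediate early lists given here did not pass camera. Only 40 of 79 ribosomal protein genes and 13 of 30 interferon genes were measured, so changes in genes without a read in some library cannot be seen. None of 22 genes for m6A writers, erasers and readers passed, over all genes or over the list alone (camera adjusted p = 0.595). The list's most abundant members Hnrnpa2b1 and Virma had log2 changes of -0.45 and 0.09. It holds Mettl14 itself (-1.83), and 13 members had a negative and 9 a positive log2 change. Mettl3, named after its values were seen, had a log2 change of -1.50. Its values were low, at 10.7 and 11.2 CPM in Ctrl 1 and Ctrl 2 and 1.84 and 5.32 CPM in cKO 1 and cKO 2. No member passed limma over all genes among 20 p53 targets (0.0982; Cdkn1a 0.29), 22 genes of the ATF4 and integrated stress response (0.245; Slc7a1 -0.26 and Slc3a2 0.014; edgeR called Slc7a11 higher, adjusted p = 0.0327), 40 cytosolic ribosomal proteins (0.962; Rpl4 -0.36 and Rpl8 -0.28), 33 translation factors (0.158; Eef2 0.32 and Eef1a1 0.34), 13 interferon response genes (0.440; Adar -0.28) or 22 immediate early genes (0.147; Myc -0.35 and Egr1 -0.068). Of 12 Notch pathway genes none passed over all genes and 1, Lfng, was lower when adjusted over the list alone (camera adjusted p = 0.595; Notch1 -0.24 and Notch2 0.45). With immediate early genes at an adjusted p of 0.0246 and translation factors at 0.00603, these 2 lists passed when Ctrl 2 was left out and under no other omission of a library. Medians and camera differed in sign for m6A, interferon, ribosomal protein, ATF4, immediate early and desmosome genes, whose medians lay below 0 and whose test pointed up relative to other genes; the means of the ATF4 and immediate early lists were above 0. None of the 13 mitochondrially encoded genes was listed.

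Markers of other cell types were read in the same way. Of 14 fibroblast markers, 3 fell (Dcn, Sparc and Postn, limma adjusted p = 0.0151, 0.0151 and 0.0252) and 6 were lower when adjusted over the list alone, and the list stood at -0.61 relative to all genes (camera adjusted p = 8.81e-06, but adjusted p = 0.502 with an estimated correlation). Without Ctrl 1 the list stood at -0.0076 (adjusted p = 0.553), and without cKO 2 at -0.59 (0.0535). Col1a1 had 397 CPM in Ctrl 1 and 25.6, 40.6 and 35.9 CPM in Ctrl 2, cKO 1 and cKO 2. Without Ctrl 1, Dcn, Sparc and Postn kept log2 changes of -1.13, -1.24 and -0.88. In the same fit Col1a1 and Col3a1 stood at 0.56 and 0.62 and Col1a2 at -0.33. Of 6 red blood cell genes, none passed limma over all genes and 2 were higher when adjusted over the list alone (Hba-a1 and Hbb-bs, which edgeR called over all genes at adjusted p = 0.0184 and 0.0494), and the list stood 1.38 above all genes (camera adjusted p = 0.00316, but adjusted p = 0.502 with an estimated correlation), but 0.37 above without cKO 1 (adjusted p = 0.646). Reads of Hba-a1 and Hba-a2, which had log2 changes of 1.5 and 0.96, cannot be told apart with certainty.

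No gene passed limma among 14 Langerhans cell and macrophage markers (camera adjusted p = 0.615; Cd74 -0.40 and Csf1r 0.20), 5 T cell markers (0.595; Thy1 -0.75 and Trdc 0.16), 10 melanocyte markers (0.595; Pmel -0.18 and Dct -0.21), 6 Merkel cell markers (0.582; Chga -0.78 and Krt20 0.013) or 5 Schwann cell and neuron markers (0.695; Erbb3 0.15 and Ncam1 -0.47). Without Ctrl 2 the Langerhans and melanocyte lists stood above other genes (adjusted p = 0.0230 and 0.0189). The means of the T cell, Merkel cell and Schwann cell lists lay below 0 although their medians and tests pointed up, and the medians and means of the Langerhans and melanocyte lists lay below 0 although their tests did. No endothelial marker of 12 and 1 skeletal muscle marker of 14 (Actc1, log2 change -0.20, at 1 to 2 reads per library) was listed, so these lists were not tested.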

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

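With 38 genes higher and 31 lower as the reference, the direction of Mettl14, Col17a1, Itga6 and Itgb4 held under every alternative run, and so did that of the 24 called genes that the naming rule gives, while other called genes named were not followed through every alternative. Upper quartile scaling, centring and TMM or DESeq2 factors moved the median log2 change of all genes from -0.245 to between -0.0399 and 0.0018, and omission of the 50 most abundant genes to -0.107. Upper quartile scaling gave 111 higher and 9 lower, median centring 105 and 8, TMM factors in limma 124 and 6, and omission of the 50 most abundant genes 71 and 12. After centring, Kremen2, Capn6, Lef1, Fxr1, Ccna2, Mthfd1, Frem2, Krt5 and Hist1h1a kept their direction but not their call. Alternatives added after the values were seen were edgeR with TMM (163 and 13), with library totals (62 and 56) and with DESeq2 size factors (159 and 17), DESeq2 (87 and 5), TMM in limma, and the block with edgeR and TMM or with centring. Of these, edgeR with TMM was the test planned for raw counts, here run on recovered reads without the planned expression filter. A filter of 10 CPM left 8301 genes and gave 14 and 9, limma without trend 0 and 0 (1033 genes at an unadjusted p under 0.05, smallest adjusted p = 0.490), an adjusted p under 0.1 gave 85 and 93, and under 0.01 it gave 5 and 1. No filter and pseudocounts of 0.1 and 5 kept counts within 37 to 38 and 30 to 31. Leaving out 1 library moved the counts between 0 and 104 higher and between 0 and 44 lower, with 0 of both without cKO 1 or cKO 2, and in each such fit the lone library is assumed to vary like the other group, and the lists called between 4 and 9 above and 4 and 8 below. With an estimated correlation 0 lists were called above and 0 below. The shared replicate numbers do not pair the samples by any label, and the deviations of equally numbered libraries correlated at 0.195 across genes and at 0.451 across 3429 genes of 50 CPM or more. With the replicate number as a block, 257 genes were higher and 582 lower, 408 and 86 with edgeR and TMM, and 415 and 162 after centring. Under the block Mettl14 (-1.83, limma adjusted p = 0.0178), Col17a1 (-0.84, 3.35e-05), Itga6 (-0.52, 0.0199) and Itgb4 (-0.87, 3.19e-05) passed, as did Col17a1 and Itgb4 with edgeR, TMM and block (-0.58 and -0.61), with centring and block (-0.63 and -0.66) and with edgeR and library totals (-0.84 and -0.88, adjusted p = 0.0458 and 0.0434). With 1 library left out Mettl14 ran from -2.18 to -1.48, Col17a1 from -0.92 to -0.76, Itga6 from -0.78 to -0.26 and Itgb4 from -1.07 to -0.67, with Itgb4 passing without Ctrl 2 (adjusted p = 0.0111). Reversals were seen in genes and lists that were not called. For these, and for the counts that moved, the cause was not tested. Across scalings, edgeR and DESeq2, Hmgcs1 (-0.0055) took 0.014, 0.14, 0.20, 0.21, 0.25, 0.26 and 0.27, and Egr1 (-0.068) took 0.078, 0.14, 0.15, 0.18, 0.21, 0.23, 0.24 and 0.25. Pmel took 0.013, 0.016, 0.032, 0.033, 0.041, 0.065 and 0.079, Dct 0.0012, 0.0086, 0.031 and 0.047, Cd74 0.033 and 0.048, Notch1 0.0078 and 0.011 and Actc1 0.012. Krt20 took -0.013 with edgeR and library totals, and Trdc -0.17 there, -0.095 with edgeR, TMM and block and -0.048 with pseudocount 5. The test of the ribosomal protein list turned under the block (median -0.012), and that of the desmosome list without the 50 most abundant genes (0.062). With 1 library left out these ran across 0: Notch1 -0.55 to 0.060, Cdkn1a -0.17 to 0.75, Slc3a2 -0.17 to 0.19, Trdc -1.21 to 1.53, Plec -0.20 to 0.48, Hmgcs1 -0.23 to 0.22, Egr1 -0.48 to 0.35, Pmel -0.65 to 0.30, Dct -0.68 to 0.27, Krt20 -0.086 to 0.11, Actc1 -0.71 to 0.31, Csf1r -0.22 to 0.61, Hba-a2 -0.46 to 2.39, Virma -0.077 to 0.26 and Cd74 -1.29 to 0.49. The list medians relative to all genes ran likewise for translation factors (-0.10 to 0.069), Langerhans cells (-0.38 to 0.51), T cells (-0.42 to 1.64), melanocytes (-0.31 to 0.50), ribosomal proteins (-0.25 to 0.21) and interferon genes (-0.10 to 0.40), while the desmosome list stayed at 0.13 to 0.35 and its test turned. The medians of the Notch (-0.22 to 0.11) and ATF4 lists (-0.023 to 0.21) crossed 0 and their tests did not turn. Of all values of named genes 1060 kept direction and side of the threshold, 147 lost the call, 42 gained it and 63 reversed, and of list values 362, 38, 4 and 12. Depth limits low genes, since 4145 genes had under 10 reads in cKO 1.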

Other observations

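Of the tests on patterns given below, those on the 50 most abundant genes, read depth, the basal keratins, the whole fibroblast list and the interstitial collagens were chosen only after the result was seen. Gene families grouped by the shared start of their symbols, a grouping made after the values were seen, held further genes beside members of the lists above. Klk5, Abca12, Mcm2 and Col17a1 are examples of such members, so the families are no independent check of those lists. Of 177 families with 8 or more measured members, 18 passed camera against all other genes at an adjusted p under 0.05, but none did with an estimated correlation (adjusted p = 0.995 for each of them). All 8 Skint genes, which encode butyrophilin-like proteins of the epidermis, lay above the median of all genes, with a family median of 1.33 relative to it (adjusted p = 8.39e-05), but of 0.22 without Ctrl 1, and Ctrl 1 had 17.1 and 21.4 CPM of Skint6 and Skint9 against 247 and 348 in Ctrl 2. The 14 Serpinb genes, inhibitors of proteases, stood 0.63 above it (adjusted p = 8.39e-05), with 4 genes higher and 1 lower, and the 8 Klk genes, kallikrein proteases of which some act in skin shedding, stood 0.63 above it (adjusted p = 0.000297), and 0.20 above without cKO 2. All 8 Abca genes, which include lipid transporters, lay above it (0.69, adjusted p = 0.00838, and 0.34 without Ctrl 1). The 22 Col genes stood at -0.41 (adjusted p = 2.06e-05, and at -0.20 without Ctrl 1), the 9 Srsf genes, which encode splicing factors, all lay below the median of all genes (-0.44, adjusted p = 0.0129, and -0.27 without cKO 1), and the 10 Mcm genes stood at -0.44 (adjusted p = 0.0133, and -0.26 without cKO 1). Near-identical members of the Skint, Serpinb, Klk and histone families can share reads.

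Some genes, named after their values were seen, differed between replicate numbers in both genotypes. With the replicate number beside group in the limma model, 191 genes were higher and 77 lower in replicate 2. These counts rest on the difference averaged over both genotypes and do not require a difference in each. Col1a1, counted as lower, had 397 and 25.6 CPM in Ctrl 1 and Ctrl 2 but 40.6 and 35.9 CPM in cKO 1 and cKO 2. Krt6a had 94.3 and 405 CPM in Ctrl 1 and Ctrl 2 and 290 and 1323 CPM in cKO 1 and cKO 2 (log2 difference between replicates 2.14, adjusted p = 2.28e-16), and Krt6b had 87.8, 477, 275 and 1783 CPM in that order. Skint3 had 3.21, 83.3, 70.1 and 190 CPM, the class I antigen gene H2-D1 11.8, 99.3, 36.9 and 95.8 CPM, and Scd1, a fatty acid desaturase, 127, 376, 97.8 and 330 CPM.

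The median gene had a log2 change of -0.245, which may stem from a few abundant genes taking more of the reads in cKO, from depth or from a broad fall. Rescaled without the 50 most abundant genes, the median of the others was -0.11, and between -0.13 and -0.070 with 1 library left out, which argues against those genes as the whole cause. With every library thinned to 542074 reads, the median of all genes was -0.239 (from -0.2394 to -0.2368 in 10 thinnings), which argues against depth. A broad fall and shifts in the shares of further genes both stay open, since values scaled to a fixed total carry no absolute level.

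The higher standing of the granular list and the lower standing of the basal list could come from GC content or coding length, from a larger share of suprabasal cells in the lysate, or from changed expression within cells after loss of Mettl14. After each library's trend on GC content and coding length was removed, both lists passed with a largest adjusted p of 4.17e-06, and their medians relative to all genes were 1.01 and -0.43, which argues against that bias, although before the correction neither passed with an estimated correlation (adjusted p = 0.498 and 0.415). A larger suprabasal share would lower the abundant basal keratins alike; Krt5, Krt14 and Krt15 had log2 changes of -1.26, -0.59 and -0.87, with a largest difference of 0.67 or 1.65 standard errors. This spread is too wide to decide, so a shift in cell share and a change within cells cannot be told apart.

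The lower standing of fibroblast markers may reflect dermal fibroblasts in the Ctrl 1 preparation, fewer fibroblasts in both cKO libraries, or lower footprints in the cells that make them. None of the list's 18 genes is in another list, but how many of them keratinocytes also express was not tested. Without Ctrl 1 the list stood at -0.0076 relative to all genes against -0.61 with it, as fibroblasts in Ctrl 1 alone would give. Col1a1 was 15.5, Col3a1 5.33 and Col1a2 3.27 times as high in Ctrl 1 as in Ctrl 2. Postn was only 1.39, Dcn 1.345 and Sparc 1.10 times as high. Dcn, Sparc and Postn stood at a median of -1.13 without Ctrl 1, but a call favours genes alike in both Ctrl libraries, so this decides nothing. Without Ctrl 1 the interstitial collagens Col1a1, Col1a2 and Col3a1 stood at 0.56, -0.33 and 0.62 (median 0.56), with Ctrl 2 as the only control, so fewer fibroblasts in both cKO libraries and lower footprints within the cells cannot be told apart.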
